A study of Solanum lycopersicum with 18 samples.

How the data were processed

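Polyadenylated RNA of callus and roots was made into stranded libraries and read paired-end on an Illumina HiSeq instrument, per the labels' protocols. The 18 libraries, in 6 groups of 3, were grouped by tissue and induction as the labels give them: uninduced, 3 h and 24 h after 10 mg/L DEX. The labels do not say whether replicates of a group came from separate plants or cultures, nor when the uninduced samples were taken, and there is 1 uninduced group per tissue. CASAVA 1.8.1 is named in the submitters' processing notes. The file headers name CLC bio software as the source of the fold changes. The aligner settings, genome build, counting method and normalization are not given in the sources used here.

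The 2 deposited files hold the same table in different formats, with a largest difference of 0 between their signed folds. Per the file headers, the authors gave for each of 4 comparisons a signed fold change, the same value as a linear ratio and the log10 of that ratio. A signed fold below 0 is the size of a reduction, and an unchanged feature has a fold of 1. The headers do not name the reference group. It was read as the uninduced samples of the same tissue, because both transgenes stood far above 1 in every comparison. The table is limited to features that the authors selected at an FDR of 0.05 and a 2-fold change in any comparison, per the deposited file's name, and 0 features have a largest absolute fold under 2. P-values, counts, depths and values per library were not analysed here, so the precision of a fold is unknown and no interval could be given.

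The tests fixed before the data were examined were a count model or a log-scale linear model over the 18 libraries, or, for a table of comparisons, the authors' adjusted p. None of these could be used, and the calls are a fold of at least 2 alone. The same limit rules out tests of the difference between tissues, the comparison of uninduced root with uninduced callus, set tests, a simulation of shared controls and counts over other splits of the samples. From the signed folds the numbers of features higher and lower, the 24 h to 3 h ratios, the overlaps between comparisons with the number expected for independent lists, and correlations across genes were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Log2 folds were taken from the ratio columns.

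Genes were named by a rule fixed before the data were examined. It takes the 10 highest and 5 lowest features of each comparison, every member of the anthocyanin structural, decoration and transport, and regulator lists, and up to 4 members of every other list in the comparison with most calls. The rule ranked list members by adjusted p, which was replaced by the size of the fold. The features at least 10-fold higher in all comparisons were named after their values were seen. The 28 lists were also fixed beforehand, as 45 identifiers, of which 31 are among the features analysed here, and as words in the table's descriptions. Short names such as DFR or AN1 come from those lists, since the table pairs identifiers with descriptions only. The words first matched inside longer words, and after this was seen matching was limited to word starts within the description. Lists of clock genes, of photorespiration, Calvin cycle and plastocyanin genes and of touch and wound responses were added after the data had been seen. The supplied RefSeq gene table matched 0 identifiers and was not used.

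For each list the median log2 fold was set beside the medians of 10000 random lists of the same size from the same column, as a description of the table and not a test over samples. On root 3 h values of 5295 features permuted to break any grouping, 40 lists of 50 members were drawn per shift. Without a shift 5% of them fell outside the central 95%. With log2 shifts of 0.5 and 1 it was 20% and 37.5%, so shifts of up to 1 are often missed. Other list sizes and columns were not simulated. Alternatives planned before the data were examined were a 4-fold threshold, no fold threshold and list members matched by identifier only. Chosen after seeing the data were the centring of each column on its median, a smaller shift of the root 3 h column and the removal of features whose folds may rest on a few reads. The latter are features with a fold of exactly 1 at either time of a tissue, or the same fold to the deposited 3 decimals at both times, 538 in callus and 48 in roots.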

Results

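The study asked how tomato (Solanum lycopersicum) transcripts respond when Rosea1 and Delila, a MYB and a bHLH regulator of anthocyanin synthesis from snapdragon, are switched on with dexamethasone (DEX), a synthetic glucocorticoid. Messenger RNA was sequenced from callus, which is undifferentiated tissue grown in culture, and from roots. Each tissue was sampled uninduced and 3 h and 24 h after induction with 10 mg/L DEX, in 3 libraries per group, which gave 18 libraries in 6 groups. The values analysed here are fold changes of 5295 features, 5293 tomato gene models and the 2 transgenes, in the authors' deposited table. It holds 4 comparisons, each read here as DEX against uninduced samples of the same tissue. None of the groups is labelled as given DEX without the transgenes. Effects of DEX itself or of handling can therefore not be told apart from those of the 2 regulators. The authors kept features at a false discovery rate (FDR) of 0.05 and a 2-fold change, as the table's name states. Values per library were not analysed here, so the depth, the spread between replicates and the significance of a fold in any 1 comparison are unknown. Higher and lower therefore mean a fold of at least 2 in that comparison, and no difference described here carries a test over samples. Counts within a gene group cover only its members among these selected features. Unchanged members are absent, so a count is not the share of a whole pathway or family. Genome positions are not given, because the build is not given in the sources used here.

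Both transgenes were higher after DEX in both tissues. This is no check of the labels, since the reference group of each comparison was read from these folds. Delila stood 69.3-fold higher in callus at 3 h and 39.2-fold at 24 h in the authors' deposited table, and 450.1-fold and 224-fold higher in roots. For Rosea the authors' deposited table gave 235-fold and 62.1-fold in callus, and 294-fold and 98.5-fold in roots. The fold at 24 h was thus 0.566 times that at 3 h for Delila in callus and 0.498 times in roots, and 0.264 and 0.335 times for Rosea. The uninduced level of a transgene can be close to 0, so folds of this size rest on a small denominator that the table does not show.

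In callus, a part of the anthocyanin transcripts already stood far above the uninduced level 3 h after DEX, and 9 of the 19 members of the structural list were higher, 3 lower and 7 under 2-fold. Of the 9 members with an identifier fixed beforehand, 8 were higher and 0 lower. Among the 10 that only their description placed in the list, 1 was higher and 3 were lower. Dihydroflavonol 4-reductase (DFR, Solyc02g085020), which makes the leucoanthocyanidin precursors of anthocyanins, led with a 14651-fold higher value in the authors' deposited table. A flavonoid 5-glucosyltransferase (5GT, Solyc12g098590) followed at 1759-fold, and a glutathione S-transferase (GST, Solyc02g081340) of the kind that carries anthocyanins to the vacuole stood at 1726-fold in the authors' deposited table. An anthocyanin acyltransferase (AAC, Solyc12g088170) was 989-fold, an O-methyltransferase (AOMT, Solyc09g082660) 591-fold and a 3-glucosyltransferase (3GT, Solyc10g083440) 574-fold higher in the authors' deposited table. Early steps of the pathway had much smaller folds, with chalcone synthase CHS1 (Solyc09g091510) at 4.67-fold and CHS2 (Solyc05g053550) at 1.67-fold in the authors' deposited table. A fold depends on the uninduced level of the gene, which is not known here. Folds therefore do not rank genes by their expression after DEX. In all, 1473 features were higher and 1240 lower at this time.

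Phenylpropanoid entry is the route from phenylalanine to coumaroyl-CoA. Among the fixed groups in callus at 3 h, 12 of its 20 selected genes were higher and 0 lower. Over all 5295 features, 1473 were higher and 1240 lower. Phenylalanine ammonia-lyases Solyc03g036470 and Solyc03g036480 stood at 6.81-fold and 6.38-fold in the authors' deposited table. The list of shikimate and aromatic amino acid synthesis, which includes the route to phenylalanine, had 7 of 11 members higher and 0 lower. Its prephenate dehydratase Solyc06g074530, of phenylalanine synthesis, stood at 5.34-fold in the authors' deposited table. Glutathione S-transferases had 21 of 34 members higher and 3 lower, and WRKY transcription factors, many of which act in stress responses, 16 of 25 higher and 2 lower. The WRKY member Solyc03g007380 was 20.4-fold higher in the authors' deposited table. The bHLH factors went the other way, with 1 of 27 higher and 10 lower. Of 121 cell wall genes 46 were lower and 16 higher. An ABC transporter of the G family (Solyc12g098210), outside the anthocyanin lists, stood at 186-fold in the authors' deposited table. The 5 lowest features were a gibberellin 2-oxidase (Solyc02g070430, 80.7-fold lower), a nodulin-like protein (Solyc01g100900, 76.7-fold), a geranylgeranyl pyrophosphate synthase (Solyc07g064660, 68.4-fold), a Ser/Thr-rich protein (Solyc04g082540, 63.3-fold) and an expansin (Solyc03g093390, 54.1-fold), all from the authors' deposited table. The synthase carried the same fold at 24 h, as 123 callus features did with a fold other than 1.

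**Figure D1:**
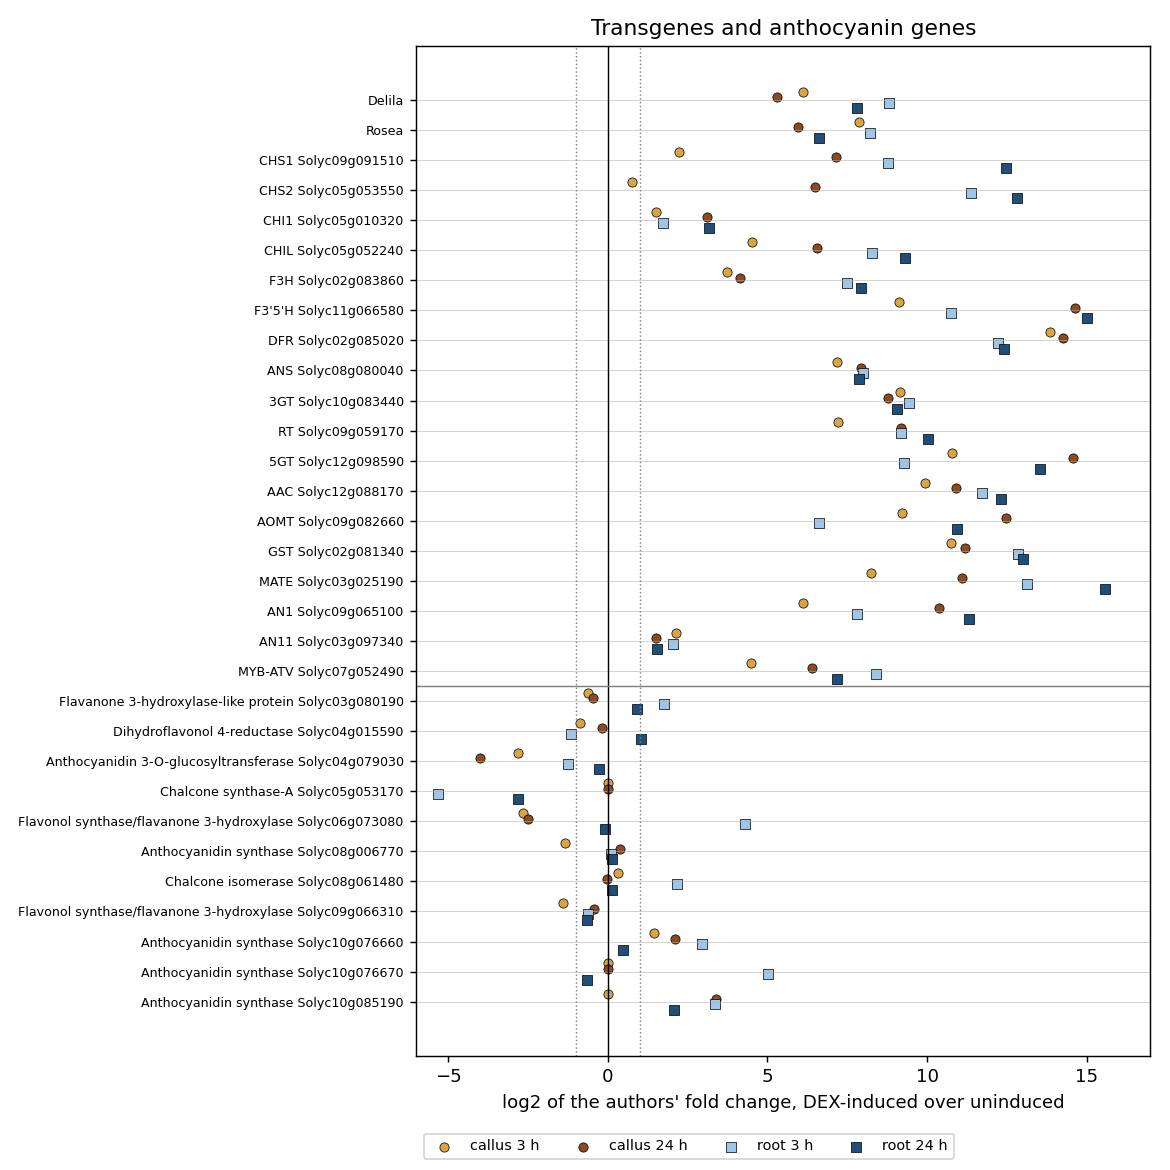
Log2 fold change, DEX over uninduced, of the 2 transgenes and all 29 members of the anthocyanin lists in the authors' deposited table, 1 symbol per comparison (circles callus, squares root, with small vertical offsets) and dotted lines at 2-fold higher and lower; a grey line sets the 11 members matched by description only below the 18 matched by identifier. Among the 18 matched by identifier, CHS2 in callus at 3 h is the only symbol between the lines, while the 11 matched by description lie on both sides of 0, and F3'5'H, 5GT, AOMT and AN1 lie farther right at 24 h than at 3 h in both tissues.

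After 24 h in callus, the flavonoid 3',5'-hydroxylase (F3'5'H, Solyc11g066580), which sets the hydroxylation of delphinidin-type pigments, was the feature with the highest fold. It stood at 25315-fold in the authors' deposited table, against 552-fold at 3 h. The 5GT was 24133-fold, DFR 19492-fold and AOMT 5663-fold higher in the authors' deposited table. CHS1 reached 142-fold, CHS2 89.7-fold and the chalcone isomerase-like gene CHIL (Solyc05g052240) 94.0-fold in the authors' deposited table. The endogenous bHLH regulator AN1 (Solyc09g065100) stood at 1328-fold, the MYB repressor MYB-ATV (Solyc07g052490) at 84.7-fold and the WD-repeat partner AN11 (Solyc03g097340) at 2.87-fold in the authors' deposited table. A defensin (Solyc07g007750) outside the pathway was listed at 1362-fold in the authors' deposited table, with exactly 1 at 3 h. In all, 955 features were higher and 1138 lower at this time.

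In callus at 24 h, 14 of 20 phenylpropanoid entry genes were higher and 0 lower, and the ammonia-lyase Solyc05g056170 stood at 10.9-fold in the authors' deposited table. MYB factors had 21 of 59 members higher and 6 lower, and 20 and 3 without features of exact or repeated folds. Of the 97 cell cycle and histone genes 45 were lower and 3 higher, against 9 lower and 5 higher at 3 h. Cell wall genes had 55 of 121 members lower and 12 higher. The photosynthesis group, used as a marker of green tissue, had 17 of 52 members higher and 3 lower at 24 h, after 2 higher and 21 lower at 3 h. Without features of exact or repeated folds it had 15 higher and 1 lower at 24 h, after 2 and 19 at 3 h. The 5 lowest features were a pectate lyase (Solyc05g014000, 211-fold lower), an unknown protein (Solyc06g076420, 188-fold), an efflux protein named corC (Solyc03g007570, 104-fold), the geranylgeranyl pyrophosphate synthase (68.4-fold) and a major latex-like protein (Solyc04g007750, 65.6-fold), all from the authors' deposited table.

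Roots at 3 h held the most features with a fold of at least 2, of which 1657 were higher and 2359 lower. Anthocyanin genes again led the higher ones. The MATE transporter Solyc03g025190, of the family that moves flavonoids into the vacuole, stood at 8993-fold, the GST at 7401-fold and DFR at 4811-fold in the authors' deposited table. AAC was 3343-fold, CHS2 2661-fold and F3'5'H 1740.3-fold higher in the authors' deposited table. CHS1 stood at 443-fold, flavanone 3-hydroxylase (F3H, Solyc02g083860) at 179-fold and anthocyanidin synthase (ANS, Solyc08g080040) at 253-fold in the authors' deposited table. Of the 19 members of the structural list 15 were higher and 2 lower, against 11 higher and 1 lower in callus at 24 h and in roots at 24 h. The 9 with an identifier fixed beforehand were all higher in each of these comparisons. The difference lay in the 10 matched by description only, of which 6 were higher in roots at 3 h and 2 in each of the others.

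Growth-related groups were mostly lower in roots at 3 h. Of 97 cell cycle and histone genes 87 were lower and 6 higher, with the histone H4 Solyc05g054610 at 11.5-fold lower and the cyclin B-like Solyc10g080950 at 10.3-fold lower in the authors' deposited table. Cell wall genes had 81 of 121 members lower and 11 higher, led by the extensins Solyc12g100110 and Solyc12g100080, which were 180-fold and 156-fold lower in the authors' deposited table. Peroxidases had 43 of 60 members lower and 9 higher, and the peroxidase Solyc01g006300 was 113-fold lower in the authors' deposited table. An unknown protein (Solyc02g076890) and a proline-rich protein (Solyc09g075410) completed the 5 lowest at 141-fold and 98.1-fold lower in the authors' deposited table. Heat shock and chaperone genes had 28 of 54 members higher and 12 lower (34 and 7 with the column centred on its median), with the heat shock transcription factor Solyc02g079180 at 28.4-fold higher in the authors' deposited table. Photosynthesis genes had 48 of 52 members lower and 0 higher. The root transporter group, aquaporins and mineral transporters, had 21 of 43 lower and 10 higher (16 and 13 with the column centred on its median).

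The median log2 fold of all features was -0.58 at root 3 h and -0.13 at root 24 h, and 0 in callus at both times. With each column centred on its median, root 3 h held 2032 higher and 1347 lower features. The share that was higher then came to 60.1%, against 41.3% without centring. Features 2-fold higher in callus only had a median root 3 h log2 fold of 1.05, and those 2-fold lower only -1.28. The median of all features 2-fold apart in callus, -0.17, reflects this mix and is no neutral reference for scaling. With only that value subtracted from the column, 1772 features were higher and 2014 lower. Lower features thus predominated under the smaller shift and not under the larger, and both shifts were chosen after seeing the data. Under centring 67 of 97 cell cycle and histone genes, 64 of 121 cell wall genes, 34 of 60 peroxidases and 38 of 52 photosynthesis genes were still at least 2-fold lower at root 3 h. The bHLH group did not keep its direction there, with 5 higher and 12 lower without centring and 6 higher and 2 lower with it.

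**Figure D2:**
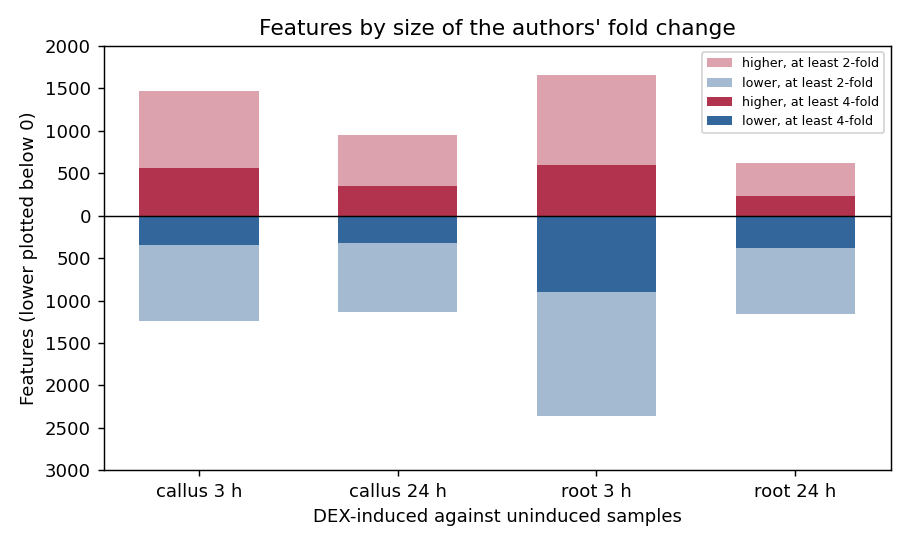
Number of features at least 2-fold (pale) and at least 4-fold (dark) higher (upward) or lower (downward) after DEX in each comparison of the authors' deposited table. Root 3 h holds 1657 higher and 2359 lower features and root 24 h 619 and 1161.

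After 24 h in roots, the MATE transporter stood at 48796-fold and F3'5'H at 32913-fold in the authors' deposited table, the 2 highest folds of that column. The 5GT was 11869-fold, the GST 8259.7-fold, CHS2 7271-fold and CHS1 5701-fold higher in the authors' deposited table. AN1 stood at 2559-fold and MYB-ATV at 146-fold in the authors' deposited table. Features with a fold of at least 2 were fewer than at 3 h, with 619 higher and 1161 lower. The ratio of their numbers, 3 h over 24 h, was 2.26 in roots and 1.30 in callus.

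Of the groups in roots at 24 h, cell wall genes had 76 of 121 members lower and 6 higher, cell cycle and histone genes 55 of 97 lower and 4 higher, and peroxidases 30 of 60 lower and 3 higher. Genes of lignin and chlorogenic acid synthesis had 32 of 60 members lower and 6 higher. Phenylpropanoid entry had 6 of 20 members higher and 0 lower, and 10 higher with the column centred on its median. Photosynthesis genes had 37 of 52 members higher and 0 lower, the reverse of 3 h, while the root transporter group had 2 of 43 higher and 13 lower. The median log2 fold of the photosynthesis genes was -2.12 at 3 h and 1.39 at 24 h, and chlorophyll a-b binding protein 3C-like (Solyc03g005780) went from 17.4-fold lower to 75.4-fold higher in the authors' deposited table. In roots 48 of the 52 were below the uninduced level at 3 h and above it at 24 h by any amount. The 5 lowest features at 24 h were a GDSL esterase (Solyc01g079160, 180.1-fold lower), a peroxidase (Solyc10g078890, 99.8-fold), a root cap protein (Solyc08g066590, 99.6-fold), a caleosin (Solyc04g005720, 97.45-fold) and a disease resistance response protein (Solyc10g008900, 91.2-fold), all from the authors' deposited table.

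**Figure D3:**
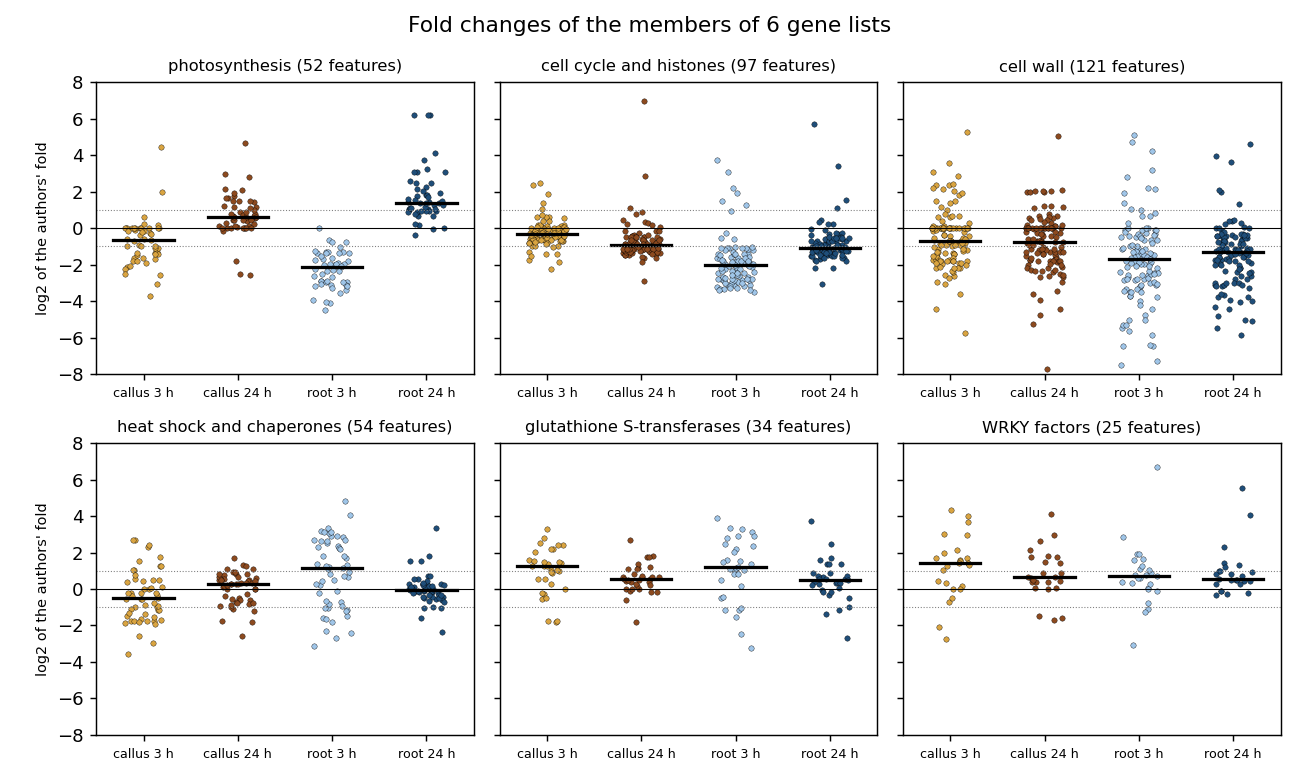
Log2 fold change of each member (points) of 6 gene groups in the 4 comparisons of the authors' deposited table, with group medians as bars and dotted lines at 2-fold; 4 points lie outside the plotted range of -8 to 8. The photosynthesis median goes from -2.12 at root 3 h to 1.39 at root 24 h, while cell cycle and cell wall medians are below 0 in all 4 comparisons.

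The course from 3 h to 24 h differed between genes of the anthocyanin pathway. From the authors' deposited table, the fold of F3'5'H at 24 h was 45.9 times that at 3 h in callus and 18.9 times in roots. The 24 h to 3 h ratio from the authors' deposited table was 19.3 in callus and 11.4 in roots for AN1, 13.7 and 19.3 for 5GT, and 9.58 and 20.1 for AOMT. CHS1 had ratios of 30.4 and 12.9, and CHS2 53.6 and 2.73, from the authors' deposited table. DFR was close to level at 1.33 and 1.13, as were the GST at 1.36 and 1.12 and F3H at 1.34 and 1.37, from the authors' deposited table. The 3GT was also close to level, with ratios of 0.761 and 0.777, and MYB-ATV had 3.77 in callus and 0.427 in roots, from the authors' deposited table. Over all features the 24 h value was at least 2-fold above the 3 h value for 794 in callus and 1379 in roots, and at least 2-fold below it for 1046 and 1218. Each ratio divides folds that share the same uninduced samples, so it compares the induced times directly, without a test. The median log2 fold of all features was -0.58 at root 3 h and -0.13 at root 24 h. Root ratios carry that difference, and these counts were not computed with centred columns.

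Callus and root shared more features than independent lists of these sizes would. At 3 h 823 features were higher in both tissues, against 461.0 for independent lists, and 727 lower in both, against 552.4, while 194 went in opposite directions. At 24 h the numbers were 345 higher against 111.6 and 562 lower against 249.5, with 101 opposite. Between 3 h and 24 h, callus shared 598 higher features against 265.7 and 551 lower against 266.5, with 106 opposite. Roots shared 433 higher against 193.7 and 920 lower against 517.2, with 128 opposite. Part of the excess between times may come from the uninduced samples that both times share, and the table holds selected features only. Across genes, which are not independent replicates, the log2 folds of callus and root had Pearson's r of 0.53 and Spearman's rho of 0.54 at 3 h, and 0.56 and 0.58 at 24 h.

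In all 4 comparisons 221 features were higher and 205 lower, of which 150 lower ones were left once features marked by exact or repeated folds were taken out. A set of 26 features stood at least 10-fold higher in every comparison, and 0 stood at least 10-fold lower in all, a limit chosen after seeing the data. The set held the 2 transgenes, 14 members of the anthocyanin lists and 10 other features. Among these were a cytochrome P450 (Solyc04g007940) at 97.9-fold, 428-fold, 82.8-fold and 466-fold in callus at 3 h and 24 h and roots at 3 h and 24 h, from the authors' deposited table. In the same order, the TBC1 domain protein Solyc02g071420 had 73.8-fold, 320-fold, 171-fold and 591-fold, and CER1 (Solyc00g278110), named for an enzyme of wax synthesis, 29.1-fold, 252-fold, 17.1-fold and 199-fold in the authors' deposited table. A cytochrome B5 (Solyc04g078140), a kind of electron donor to P450 enzymes, had 15.1-fold, 59.6-fold, 23.7-fold and 82.7-fold in the authors' deposited table. The others were a pectinesterase (Solyc01g098940), a glutamate receptor-like channel (Solyc06g063190), an FAD-binding protein (Solyc06g065060), a heme-binding protein (Solyc07g061800), a receptor-like kinase (Solyc08g068250) and a heat stress transcription factor (Solyc10g079380).

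The decoration and transport list had 7 of 8 members higher in every comparison, and its other member, an anthocyanidin 3-O-glucosyltransferase (Solyc04g079030), was 7.03-fold lower in callus at 3 h and 16.1-fold lower at 24 h in the authors' deposited table. The rhamnosyltransferase RT (Solyc09g059170) of that list stood at 149-fold and 582-fold in callus and 581-fold and 1043-fold in roots, and chalcone isomerase CHI1 (Solyc05g010320) of the structural list at 2.82-fold, 8.61-fold, 3.31-fold and 8.93-fold, in the authors' deposited table.

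The structural list held 9 members with an identifier fixed beforehand, among them the 3GT, whose description matched this list too, and 10 that only their description placed there. The 9 were higher in every comparison except for CHS2 in callus at 3 h. The 10 had 1 higher and 3 lower in callus at 3 h, 2 higher and 1 lower at 24 h, 6 higher and 2 lower in roots at 3 h, and 2 higher and 1 lower at 24 h. The 3 lower in callus at 3 h were the flavonol synthases or flavanone 3-hydroxylases Solyc06g073080, at 6.34-fold lower, and Solyc09g066310, at 2.66-fold lower, and the anthocyanidin synthase fragment Solyc08g006770, at 2.52-fold lower, in the authors' deposited table. Solyc06g073080 was 5.64-fold lower in callus at 24 h and 19.8-fold higher in roots at 3 h in the authors' deposited table. A chalcone synthase-A (Solyc05g053170) was 39.9-fold lower in roots at 3 h and 7.06-fold lower at 24 h in the authors' deposited table. A further dihydroflavonol 4-reductase (Solyc04g015590) was 2.22-fold lower in roots at 3 h and 2.06-fold higher at 24 h in the authors' deposited table. The anthocyanidin synthases Solyc10g076660, Solyc10g076670 and Solyc10g085190 were 7.78-fold, 32.2-fold and 10.3-fold higher in roots at 3 h in the authors' deposited table. There a flavanone 3-hydroxylase-like protein (Solyc03g080190) stood at 3.37-fold and a chalcone isomerase (Solyc08g061480) at 4.52-fold higher in the authors' deposited table. All 3 regulators among the features analysed here, AN1, AN11 and MYB-ATV, were higher in the 4 comparisons. Chalcone synthases, ammonia-lyases, extensins and histones are families of similar genes, and the counting method is not given in the sources used here, so values of single members are uncertain.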

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

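The tests of shoot tissue, with and without plastocyanin, of time of day, of light and of repeated folds, and the centring behind the number of root features, were chosen only after the result was seen, as was the limit for naming a group here (at least 10 members and medians at least 0.5 on the log2 scale on opposite sides of 0).

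Heat shock and chaperone genes had a median log2 fold of -0.52 in callus at 3 h and 1.13 in roots at 3 h. The medians lie on opposite sides of the uninduced level in the 2 tissues, and the difference was not tested over samples.

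Photosynthesis genes lay on opposite sides of the uninduced level at the 2 times, with median log2 folds of -2.12 and 1.39 in roots and -0.65 and 0.63 in callus, a difference that was not tested over samples. Of the 86 features at least 2-fold lower at root 3 h and at least 2-fold higher at root 24 h, 35 were in this group. A difference in light or time of day between samples stays open, since the group also moved in callus, with -0.65 at 3 h. Less and then more shoot tissue in the root samples stays open too. A list of 20 genes was matched by words for photorespiration, the Calvin cycle and plastocyanin. Its medians were -1.41 at root 3 h and 0.53 at root 24 h, and -1.41 and 0.64 for the 16 without plastocyanin in the description. In callus at 3 h and 24 h the medians were -0.62 and 0.25 for the 20, at percentiles 4.32 and 86.79 of random lists. For the 16 they were -0.44 and 0.29. The list thus had the same signs in both tissues, and its root medians cannot tell shoot tissue from light or time of day. The root transporter group had medians of -0.99 at root 3 h and -0.53 at root 24 h (-0.41 and -0.39 with the columns centred). It was thus opposite to the photosynthesis group at 24 h and not at 3 h. Shoot tissue would not reach callus, and the control sampling times are not given in the sources used here. A response to the induced regulators is confounded with time after DEX and with DEX itself, and was not tested.

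Roots at 3 h held 2.26 times as many features 2-fold apart as roots at 24 h, most of them lower. A shift of the authors' scaling as the whole cause of the number is argued against by a ratio of 1.93 after centring. Folds resting on a few reads stay open: the ratio was 2.27 without the 48 root features with exact or repeated folds, but their removal could not have brought it under 2.23, so the limit of 1.5 set beforehand for excluding this was wrong. For the direction, scaling stays open, as features 2-fold apart in callus had a median root 3 h log2 fold of -0.17 (95% bootstrap interval over features -0.26 to -0.09), which is neither 0 nor the whole-column median of -0.58, and they go both ways. Time of day cannot be told apart from the groups, with the mean difference of 12 clock genes at percentile 57.2 of random lists, and a biological response to 3 h of DEX stays open and untested.

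In callus, many folds repeat at the same values, and 300 features have a fold of exactly 1 at both times, against 12 in roots. Single reads over a fixed floor are a candidate explanation: 69 of 122 features equally lower at both times sit near 3.43-fold, and 2 further sets hold features at exactly 1 at one callus time and higher at the other. Of the 74 values of these 3 sets between the lowest cluster and a fold of 14, 90.5% lie within a fold difference of 0.3 from a whole number of steps, against 22.0% for a uniform spread, and values over 14 were not tested. The tolerance and the upper limit were set after the steps were seen, and no other explanation was tested. Without features of exact or repeated folds, callus held 1425 of 1473 higher and 1118 of 1240 lower features at 3 h, 890 of 955 and 1016 of 1138 at 24 h, and 429 of the 551 lower at both times.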

How the results depend on the processing

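Centring each column on its median, shifting root 3 h by a smaller value and leaving out features whose folds may rest on a few reads were chosen only after the result was seen. No paired analysis was possible because the table holds 1 fold per comparison and no value per replicate. For the same reason the planned changes of filter, pseudocount, normalization, samples in the fit, left-out replicates, adjusted p threshold and correlation in set tests were not run, and depth cannot be judged. Every count depends on the threshold by construction. At 4-fold, higher and lower features numbered 560 and 351 in callus at 3 h, 351 and 318 in callus at 24 h, 601 and 902 in roots at 3 h, and 230 and 384 in roots at 24 h. With no threshold they numbered 2384 and 2544, 2464 and 2483, 2264 and 3005, and 2325 and 2946 in the same order. Centring could not change callus, whose column medians were 0, the log2 value of a fold of exactly 1. It gave 748 higher and 1002 lower features in roots at 24 h, and moved the lower features of roots at 3 h from 2359 to 1347, by the shift of the column's median. With only the median of features 2-fold apart in callus subtracted, roots at 3 h had 1772 higher and 2014 lower. From 3 h to 24 h, 363 features were higher and 342 lower at 4-fold in callus and 464 and 378 in roots, and 2109 and 2763, and 2722 and 2551, with no threshold. Shared higher and lower features at 4-fold were 245 and 108 between tissues at 3 h, 107 and 76 at 24 h, 195 and 125 between times in callus, and 135 and 219 in roots. With no threshold they were 1795 and 2140, 1764 and 1992, 1806 and 1952, and 1706 and 2397. Without the features whose folds may rest on a few reads, each of these counts stayed within 1.5 times, with 1425 higher and 1118 lower in callus at 3 h, 890 and 1016 at 24 h, 1647 and 2348 in roots at 3 h, and 607 and 1150 at 24 h. Of the list counts, 216 stayed within 1.5 times and 8 did not under that removal, 67 and 157 at 4-fold, and 23 and 25 with members matched by identifier only.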

Other observations

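The lists of clock, photorespiration and touch genes described here were chosen only after the result was seen, and the test of neighbouring identifiers was set before its value was seen.

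Cytochrome P450 genes had 38 of 110 members higher and 25 lower in callus at 3 h and 41 higher and 47 lower in roots at 3 h (47 and 34 with the column centred on its median). Glycosyltransferases had 31 of 80 higher and 24 lower in callus at 3 h and 32 higher and 32 lower in roots at 3 h (35 and 15 centred). MATE and ABC transporters had 16 of 68 higher and 16 lower in callus at 3 h and 22 higher and 29 lower in roots at 3 h (27 and 10 centred). Ethylene response genes had 31 of 80 higher and 20 lower in callus at 3 h and 28 higher and 29 lower in roots at 3 h (36 and 16 centred). The ethylene-responsive factor Solyc07g042230 stood at 13.7-fold in callus and 129-fold in roots at 3 h in the authors' deposited table. Sugar metabolism and transport genes had 9 of 13 higher and 2 lower in roots at 3 h (10 and 1 centred), with the trehalose-6-phosphate phosphatase Solyc04g072920 at 18.8-fold in the authors' deposited table. In roots at 3 h auxin response genes had 14 of 51 higher and 19 lower (18 and 7 centred), gibberellin, abscisic acid and cytokinin genes 15 of 36 higher and 12 lower, jasmonate genes 6 of 15 higher and 7 lower (6 and 4 centred), and pathogenesis-related genes 11 of 45 higher and 18 lower (15 and 8 centred). Flavonol genes had 1 of 3 higher and 1 lower there, and proton pumps 1 of 2 higher and 1 lower.

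Touch and wound response genes, 93 of which also belong to fixed lists, had 50 of 106 members higher and 21 lower in callus at 3 h, 21 and 19 at 24 h, 42 and 32 in roots at 3 h (55 and 21 centred), and 19 and 21 at 24 h (22 and 18 centred). Clock genes had 5 of 12 higher and 2 lower in callus at 3 h and 6 higher and 6 lower in roots at 3 h (6 and 1 centred). Photorespiration, Calvin cycle and plastocyanin genes had 2 of 20 higher and 13 lower in roots at 3 h (4 and 9 centred) and 4 higher and 1 lower at 24 h. Of 104 medians of fixed lists, 30 lay above and 16 under the central 95% of random lists, against 5.2 outside expected for unrelated features. Lists share members, and members of a list may move together. The medians are thus not independent, and 5.2 is no measure of chance for lists of related genes.

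Gene models with neighbouring identifiers may move together. Of 713 pairs of adjacent models both at least 2-fold apart in roots at 3 h, 70.4% had the same direction, against a median of 51.5% and an upper limit of the central 95% of 55.0% over 1000 permutations. Among the 556 pairs with different descriptions the share was 64.9%. Shared reads between tandem copies, and shared regulation of neighbours, were not told apart by this test.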
